A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

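H4K16ac ChIP-seq was carried out in wild-type budding yeast and in cells labelled nhp6ab, with 2 replicates each according to the titles, 4 libraries in all. Per the labels' protocols, cells grew exponentially in rich glucose medium (YPD), were cross-linked with formaldehyde and broken with glass beads, chromatin was sheared by sonication, and complexes were isolated with an antibody against acetylated H4K16. Libraries were amplified by PCR and sequenced on an Illumina instrument. Per the submitters' processing notes, FastQC and Bowtie were used with genome build R64, with no versions given. The nucleosome caller, the read filters and the way replicates were combined are not given in the sources used here. No input library was used here, so counts reflect chromatin recovery, copy number and mapping as well as acetylation.

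The authors deposited 1 table per genotype, each named in the description of both replicates of that genotype, with a chromosome, a start, an end and a read count per listed nucleosome. Per the file headers these values are read counts, and they are whole numbers with different totals, so they were treated as counts that were not normalized. Because each table has a single column for both replicates, a count test with replicates could not be run. The planned test between genotypes was replaced, as laid down before the data were examined, by ratios with counting intervals. Intervals were 120 to 160 bp wide, and 57.6% of those in WT and 42.7% in nhp6ab had the full 160 bp. Of the listed nucleosomes, 41.1% in WT and 39.1% in nhp6ab overlapped the next, so a read may be counted more than once and the counting intervals are then too narrow. Each table lists its own nucleosomes and their positions differ, but the reads from which they were called are not given. The lowest listed count was 14 in WT and 0 in nhp6ab. A nucleosome that is not listed is not a count of 0, so genes listed in a single table received no ratio. Of genes with at least 100 counts, 42 were of this kind, 30 listed in WT only and 12 in nhp6ab only. This requirement of a nonzero count in both tables was added after the files were seen.

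Counts were scaled to the table total. The log2 ratio of nhp6ab to WT was given with an exact conditional binomial 95% interval, which covers counting error only since PCR reads without molecular identifiers are not independent molecules. The totals were 26526939 for WT and 20293261 for nhp6ab, the latter 76.5% of the former. A nucleosome at the median count had a counting error of 4.76% in WT and 5.31% in nhp6ab. For a gene, all listed nucleosomes with a midpoint from 500 bp upstream of the open reading frame start to its end were summed. A gene was measured with at least 100 counts over both tables. It was called higher or lower at an absolute log2 ratio of at least 1 with an interval that excluded 0. Levels are mean counts per listed nucleosome divided by the table's median for genes, and median counts divided by the table's median for regions. Single nucleosomes were paired between tables by the nearest midpoint within 50 bp, one to one, with at least 10 counts over both. Distances to chromosome ends were divided at 5, 10, 20 and 30 kb, with the ends taken as position 1 and the largest coordinate in the annotation or the tables. Positions along genes were divided at 500 and 1000 bp. Silent mating loci included 1000 bp on each side, and tRNA genes 500 bp.

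Gene positions and symbols came from an R64 gene table, with the strand read from the systematic name, for 6408 genes outside the mitochondrial genome and the ribosomal RNA genes. Coordinates are given as the tables give them. Of 723 names on the gene lists, which were written before the data were examined, 718 matched. A list's median was set against 10000 random lists of the same size drawn with the same numbers of genes from 20 bins of mean count, and sets of nucleosomes likewise. Lists with fewer than 3 measured genes, the NHP6 genes and the silent mating loci, received no percentile. Genes were named by a rule fixed in advance: the 12 highest and 12 lowest ratios among measured genes, the 2 highest and 2 lowest of each list, and NHP6A and NHP6B. The value of 1 gene that this rule names is not reported here. TEF1, FAS1, HHT1, HHT2, MRM1, DED1, HOP2, CSN9, YNL146C-A, YNCB0012W and HSH49 fall outside the rule and were chosen after their values were seen, and LEU2, TRP1, LYS2, MET17 and CAN1 were added as genes often used as strain markers.

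The scripts were tested on simulated tables with the real totals and gene counts. For the per-gene comparison of nhp6ab with WT, 95.2% of the true ratios of 6134 simulated genes fell inside their 95% interval. Of genes changed 2-fold, 100% had an interval that excluded 0, and of those changed 1.25-fold, 97%. Among unchanged genes the share was 4.79%. Of random lists of 25 genes, 4.5% fell outside the central 95%, and 96% of lists raised by 0.2 were found above it. Pairing recovered 100% of the retained nucleosomes in the simulation. Each of these had a true partner by construction, so this share does not measure how well the separately listed real tables were paired. In those, 84.5% of the WT list and 88.7% of the nhp6ab list found a partner. The simulation holds no variation between replicates, which the deposited tables do not show.

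Alternatives set before the data were examined were scaling to the median ratio over genes, open reading frames or upstream sequence alone, other minimum counts (none, 50 or 500), pairing within 25 bp, a threshold of 0.58, the median over chromosome ends, paired nucleosomes only, open reading frames of at least 1500 bp, the mean count per listed nucleosome for genes, and random lists drawn more than 30 kb from chromosome ends. Leaving out chromosome XII, centring each chromosome on its own median, and the mean count per listed nucleosome for lists and regions were chosen after seeing the data. Centromeres and LTR and Ty elements were not analysed here, since the gene table holds no coordinates for them. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.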

Results

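Acetylation of lysine 16 of histone H4 (H4K16ac), a mark of open chromatin that the deacetylase Sir2 removes at silenced loci, was profiled by ChIP-seq in budding yeast growing exponentially in rich medium. Wild-type (WT) cells were compared with cells labelled nhp6ab, a genotype named after NHP6A and NHP6B, the paralogous genes of the small HMGB-type DNA-bending proteins that act with the FACT histone chaperone. The labels name 4 libraries, 2 per genotype. The values came as a single column of read counts over called nucleosomes for each genotype, so the spread between replicates is unknown, no test between genotypes was made, and every interval given here covers counting error only. The WT table listed 60557 nucleosomes with 26526939 counts in all and a median of 442 counts per nucleosome (interquartile range 356 to 522). The table labelled nhp6ab listed 57674 nucleosomes, 4.76% fewer, with 20293261 counts and a median of 354 (283 to 421). The listed nucleosomes covered 8.59 Mb of the R64 genome in WT and 7.99 Mb in the other table, with a median spacing of 162 bp in both. Log2 ratios are nhp6ab over WT after scaling to the table totals. A change of the mark shared by the whole genome cannot be seen after this scaling. Each ratio therefore describes a share of the counts and not an absolute level. Ratios are of summed counts unless stated. Because each table lists its own nucleosomes, a sum also moves with the number listed. The ratio of the mean count per listed nucleosome is therefore added for regions and for some lists and genes. With fewer nucleosomes listed in nhp6ab, this mean ratio lies above 0 for the genome as a whole, at 0.07 beyond 30 kb from chromosome ends. A small positive mean ratio is therefore no rise, and a changed sign alone is no changed direction. Among the 134 genes named by the rule in the methods, the mean ratio is given, as a range for 9 tRNA genes, wherever it reversed the sign (16 genes) or differed by at least 0.4 (44 genes).

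The genes that give the mutant its name were examined first, as a check of the labels. Over the NHP6A open reading frame (YPR052C, chromosome XVI, 665693 to 665974), 592 counts were found in WT and 260 in the table labelled nhp6ab, which is 57.4% of the count expected from the table totals. Over NHP6B (YBR089C-A, chromosome II, 426190 to 426489), the counts were 882 and 564, or 83.6% of expectation. With 500 bp of upstream sequence included, the log2 ratio was −1.005 for NHP6A (95% interval −1.13 to −0.88) and −0.17 for NHP6B (−0.26 to −0.07), or −0.43 for NHP6B by the mean per listed nucleosome. Both genes were thus lower in the table labelled nhp6ab, but neither was without reads, so the counts do not show a loss of the whole open reading frames. The summed NHP6B ratio was ordinary, at percentile 24.6 of measured genes, or 3.24 by the mean. Over NHP6B, the nhp6ab nucleosome at 426207 to 426367 had a higher scaled count than its WT counterpart (15.5 against 12.6). The nucleosome at 426347 to 426507 had a lower one (12.3 against 20.6). By the sum, NHP6B is therefore a weak check of the labels. The labels give no structure of the alleles, so these counts neither settle nor refute the labels. Whether a library is mixed or mislabelled was not tested, and reads of WT cells in the table labelled nhp6ab would bring ratios closer to 0. Each direction given is therefore that of the tables as labelled. HIS3 and URA3, genes often used as markers in strain construction, were higher in the table labelled nhp6ab by 1.57 (1.47 to 1.68) and 1.04 (0.98 to 1.11) over their open reading frames, or 1.16 and 0.78 by the mean per nucleosome.

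**Figure D1:**
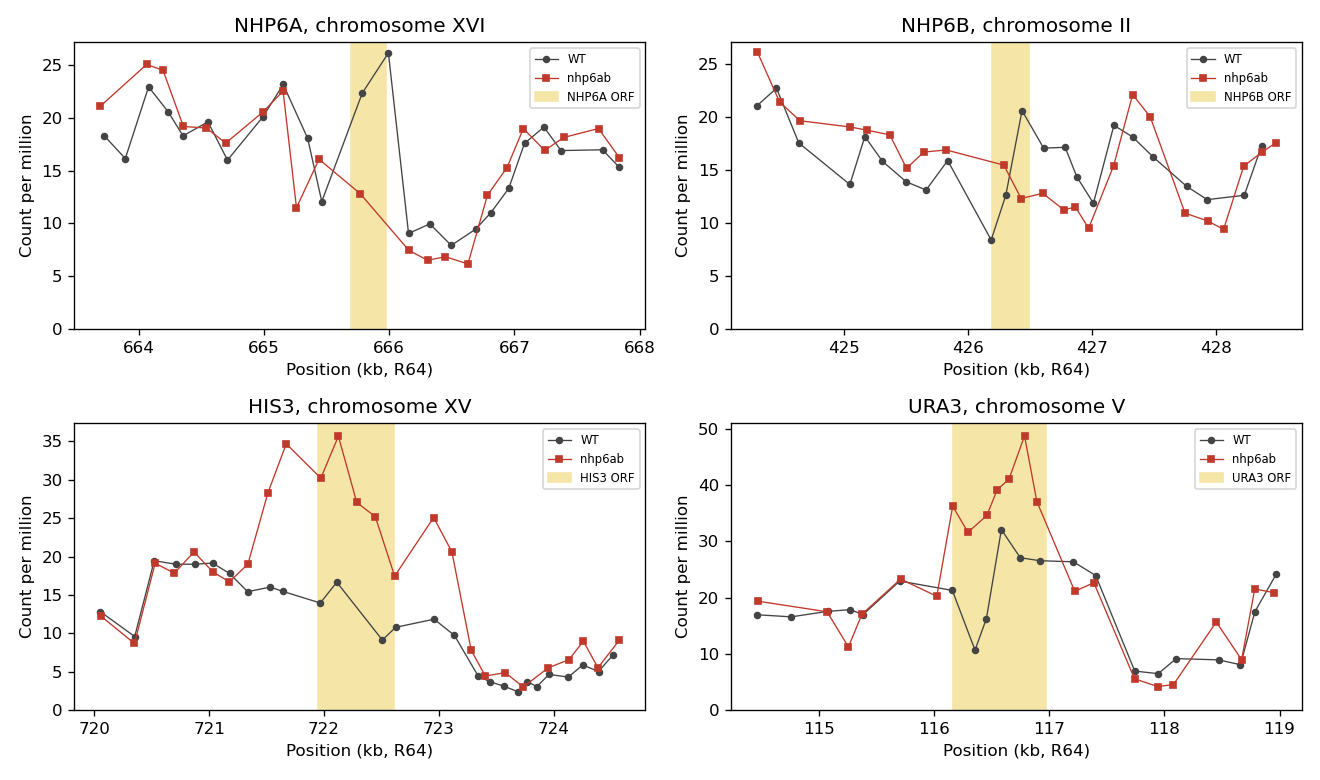
Counts scaled to the table total (CPM) at the midpoint of each listed nucleosome (vertical axis) against position in kb (horizontal axis) around NHP6A, NHP6B, HIS3 and URA3, with WT in grey circles, nhp6ab in red squares and the open reading frame shaded. Counts over NHP6A and NHP6B are lower in the nhp6ab table (260 against 592 and 564 against 882 before scaling) but not 0, while those over HIS3 and URA3 are higher (2397 against 1054 and 4718 against 2991).

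Chromosome XII carried a larger part of the H4K16ac counts in the table labelled nhp6ab than in WT, and the other chromosomes held similar parts in both. That chromosome held 8.51% of the WT counts and 10.9% of the counts labelled nhp6ab, a log2 ratio of 0.36 (0.36 to 0.37) or 1.29-fold. Its share of listed nucleosomes was 8.78% and 8.67%, its covered length 750 kb and 695 kb, and its mean count per nucleosome 424 and 444. The other 15 chromosomes lay between −0.05 and 0.00. Of 517 measured genes on chromosome XII, 90.3% had a ratio above 0, against 40.8% of 5617 genes elsewhere. Among nucleosomes matched between the tables the median was 0.44 on chromosome XII and 0.02 on the other chromosomes. All 42 bins of 25 kb on chromosome XII lay between 0.26 and 0.51, above the 95th percentile (0.07) of the 435 bins on other chromosomes. Genes on chromosome XII are named as such, since their ratios share this shift.

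**Figure D2:**
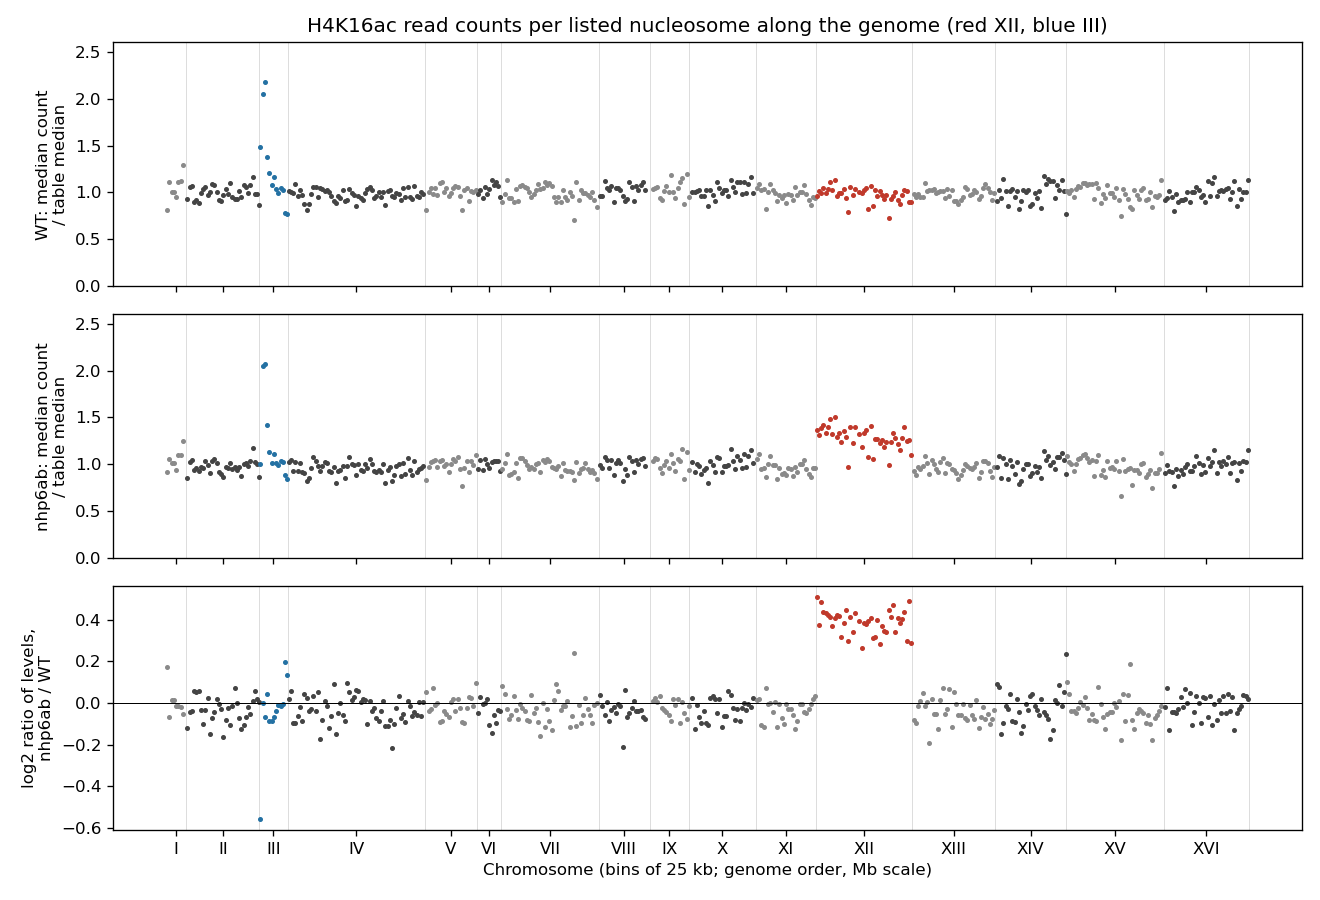
Median count per listed nucleosome in bins of 25 kb divided by the table's median, for WT (top) and nhp6ab (middle), and the log2 ratio of these levels (bottom), in genome order, each point being a bin with chromosome XII in red and chromosome III in blue. The chromosome XII bins lie between 0.26 and 0.51 in the bottom panel, and the left arm of chromosome III reaches about 2 times the median in both tables (2.06 and 2.10 between 15 and 85 kb).

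Most genes carried the mark at similar relative levels in both tables. The median log2 ratio over 6134 measured genes was −0.02, with an interquartile range of −0.16 to 0.11, and 94.2% of genes lay within 0.58, or 1.5-fold, of 0. A typical gene had 4113.5 counts in WT and 3083.5 in the other table over 9 listed nucleosomes, and the 95% interval typically reached 0.07 to either side. At least 2 times higher in the table labelled nhp6ab, with an interval that excluded 0, were 20 genes, 10 of them protein-coding and 10 tRNA genes. The 66 genes at least 2 times lower comprised 38 protein-coding, 24 tRNA and 4 snoRNA genes. The mean count per listed nucleosome passed the same limit for 8 of the 20 and 31 of the 66. Few nucleosomes lay behind many of these calls: 15 of the 20 had 3 or fewer in the table labelled nhp6ab, and 42 of the 66 had 3 or fewer in WT.

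Transfer RNA genes, short units transcribed by RNA polymerase III, stood at both extremes. The highest ratio was that of YNCI0007C (chromosome IX, 300228 to 300300) at 3.06 (2.72 to 3.42), with 80 counts in WT and 512 in the table labelled nhp6ab over 1 nucleosome in each. SUP16 (chromosome XVI, 689565 to 689646), also with 1 nucleosome in each table, had 99 and 381 counts and a log2 ratio of 2.33. YNCP0007C at 2.57, YNCM0035C at 2.43, YNCK0016W at 1.95, YNCB0002W at 1.88 and YNCK0021W at 1.504 had one more listed nucleosome in the table labelled nhp6ab than in WT. By the mean per nucleosome these were 1.57, 1.43, 0.95, 0.88 and 0.92, and over the gene body alone all 5 turned negative, between −0.57 and −0.19. Lowest of all was TRT2 (chromosome XI, 46735 to 46806), with 1235 and 68 counts, a ratio of −3.80 (−4.17 to −3.44), or −2.21 by the mean, and 3 nucleosomes listed in WT against 1. YNCG0020C had 1 nucleosome in each table and a ratio of −3.20. The remaining tRNA genes among the lowest were YNCB0004W (−3.42), YNCP0020W (−3.37), YNCE0016C (−3.05), YNCG0027W (−3.04), YNCH0003C (−2.96), YNCB0011C (−2.70), YNCK0007W (−2.69), SUF5 (−2.55) and YNCE0018W (−2.51), each with 1 nucleosome in the table labelled nhp6ab and 2 or 3 in WT, and with means per nucleosome between −2.42 and −1.10. Over all 225 measured tRNA genes the median was −0.08 by the sum and −0.09 by the mean. Because tRNA genes belong to families of near-identical copies and often lie beside repeated Ty sequences, the placement of their reads is uncertain.

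Among protein-coding genes, the highest ratio was that of RPP0 (YLR340W, chromosome XII, 805887 to 806825), which encodes the P0 protein of the ribosomal stalk. Its log2 ratio was 1.57 (1.46 to 1.67), with 1022 counts over 5 nucleosomes in WT and 2316 over 8 in the table labelled nhp6ab. The mean per nucleosome gave 0.89, and centring on the chromosome's median left 1.19 of the summed ratio. IMD2 (YHR216W, chromosome VIII, 554396 to 555967), an inosine monophosphate dehydrogenase gene of guanine nucleotide synthesis near the chromosome end, stood at 1.53 (1.26 to 1.81) by sum and mean alike. HIS3, of histidine biosynthesis, was at 1.35 (1.27 to 1.43), or 1.08 by the mean. For PAU24, of the seripauperin family, 1.502 by the sum went with 0.50 by the mean, and for the uncharacterised YGL188C-A 1.37 went with 0.05. The lowest protein-coding gene was TEF2 (YBR118W, chromosome II, 477671 to 479047), one of a pair of genes for translation elongation factor EF-1 alpha, at −2.84 (−3.39 to −2.34) from 328 and 35 counts, or −1.26 by the mean. Reads of TEF2 and its near-identical partner TEF1 cannot be separated with certainty, and the same limit applies to IMD2 and PAU24 within their families.

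Single nucleosomes could be paired for 84.5% of the WT list and 88.7% of the other list, 51169 pairs in all. Their median log2 ratio was 0.04 (SD over pairs 0.34). At least 2 times higher in the table labelled nhp6ab were 164 pairs, of which 98 lay on chromosome XII, and without that chromosome 66 pairs remained. At least 2 times lower were 388 pairs, 14 of them on chromosome XII. Upstream sequence was frequent among the lower pairs: 180 of the 388, or 46.4%, lay within 500 bp upstream of an open reading frame, where 11.2% of all pairs lay. Of the 164 higher pairs, 10 were upstream.

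Position along the gene was compared in 4 classes measured from the start of the open reading frame. In WT the level was highest in the first 500 bp of the open reading frame, at 1.11 times the table's median and was 1.02 from there to 1000 bp and 0.96 beyond. Upstream it was 0.90. In the table labelled nhp6ab the levels in the same order were 1.09, 1.03 and 0.97, and the upstream level was 0.84. The summed counts upstream were lower in the table labelled nhp6ab by a log2 ratio of −0.22 (−0.22 to −0.22), where 6422 nucleosomes were listed against 7194 in WT, 10.7% fewer, over 916284 and 1059264 bp. The mean per listed nucleosome gave −0.06 there. Inside open reading frames the sums gave 0.04, 0.06 and 0.01 and the means 0.05, 0.11 and 0.10, with 0.98%, 3.20% and 5.84% fewer nucleosomes listed. By the mean, upstream sequence at −0.06 thus lay below the 0.05 to 0.11 found inside open reading frames. The upstream difference in the sum went both with fewer listed nucleosomes and with a lower count per nucleosome. Without chromosome XII the upstream ratio was −0.25 and that of the first 500 bp 0.00.

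Chromosome ends, where Sir proteins silence genes and H4K16ac is low, held a slightly larger share of the counts in the table labelled nhp6ab. Within 5 kb of an end the level was 0.41 times the median in WT and 0.44 in the table labelled nhp6ab, with 121 and 138 listed nucleosomes over 16636 and 18634 bp. The ratio of summed counts was 0.34 (0.31 to 0.36), and of means 0.15. Between 5 and 10 kb the ratio was 0.12 (0.11 to 0.13), with a mean ratio of 0.15 and levels of 0.88 and 0.97. From 10 to 20 kb it was 0.04 and from 20 to 30 kb 0.03, with 0.11 by the mean in both, and beyond 30 kb it was −0.00 by the sum and 0.07 by the mean. Matched nucleosomes within 5 kb had a median of 0.26 over 99 pairs, above all 10000 random sets of the same size and mean count. Those from 5 to 10, 10 to 20 and 20 to 30 kb, with medians of 0.15, 0.09 and 0.09, also lay above all of their random sets. The random sets were drawn as single nucleosomes from the whole genome, whereas these pairs are neighbours clustered on the ends. Neighbours may not vary independently, so the percentiles overstate the evidence. Of 13 ends with listed nucleosomes within 5 kb, 11 had a ratio above 0, as did 19 of 23 between 5 and 10 kb, 17 of 30 between 10 and 20 kb and 15 of 30 between 20 and 30 kb. The single ends within 5 kb ranged from −1.25 to 1.15. Ends were taken from the annotation and the tables rather than from chromosome lengths, and repeats near ends make read placement uncertain.

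**Figure D3:**
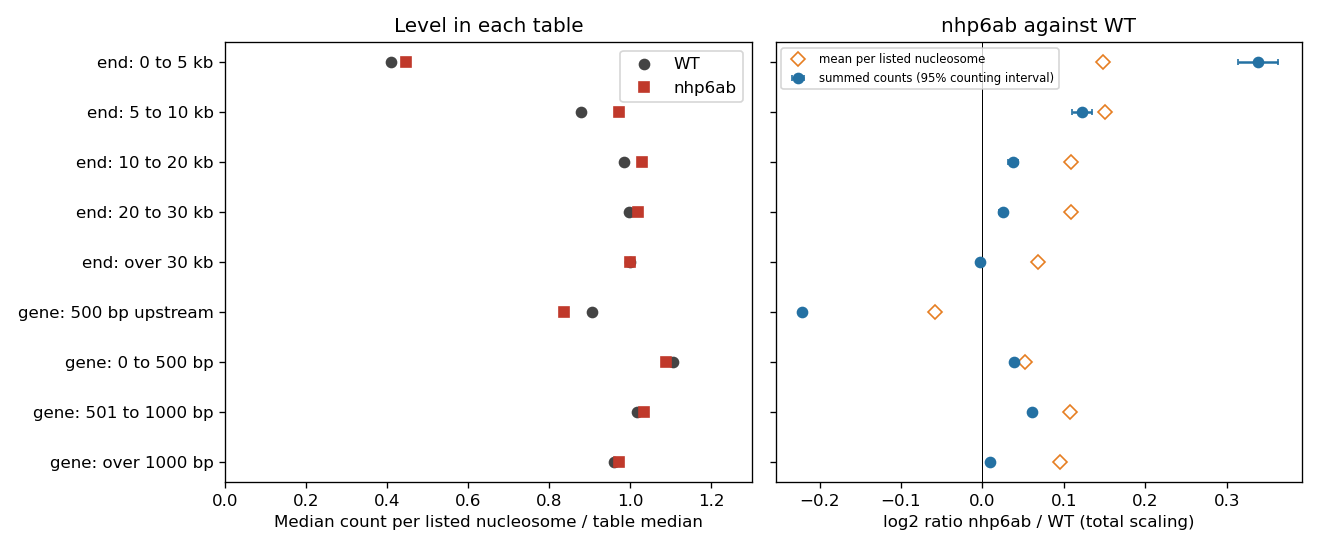
Left, median count per listed nucleosome divided by the table's median for 5 distances from chromosome ends and 4 positions along genes, with WT in grey circles and nhp6ab in red squares. Right, log2 ratio of nhp6ab to WT for summed counts (blue, with 95% counting intervals) and for the mean per listed nucleosome (orange diamonds), with the highest sum at 0.34 within 5 kb of ends and the lowest at −0.22 upstream of open reading frames.

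The silent mating loci were thinly covered. Around HML, a silent copy of mating-type information, 3 nucleosomes with 324 counts were listed in WT, over 464 bp. The table labelled nhp6ab listed 2 with 61 counts, over 306 bp. The log2 ratio was −2.02 (−2.44 to −1.62) and −1.44 by the mean. These nucleosomes lay from 14154 to 14846 in WT and from 14151 to 14690 in nhp6ab. That is the right part of a window with 1000 bp flanks, so the ratio does not describe the locus as a whole. At HMR, the other silent copy, 1 nucleosome in each table held 48 and 21 counts, a ratio of −0.81 (−1.62 to −0.04). These loci share sequence with the active mating-type locus, so the origin of their reads is uncertain. No nucleosome was listed over the ribosomal DNA in either table, which is not a count of 0. Within 500 bp of tRNA genes the ratio was −0.13 (−0.14 to −0.12) by the sum over 1022 and 981 nucleosomes and 152732 and 140947 bp, and −0.07 by the mean. Their 845 matched pairs had a median of −0.10, below all 10000 random sets. These sets were matched on mean count and not on position along genes. Since sequence upstream of open reading frames was lower in general, the percentile shows nothing particular to tRNA genes.

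Gene groups were compared through 28 lists with at least 3 measured members, each list's median log2 ratio being set against 10000 random lists of the same size and mean count. For each list the members higher or lower beyond counting error were counted. Outside the central 95% of the random lists were 3 lists on the high side and 3 on the low side, where chance alone would place 1.4. The percentiles describe these libraries and are not tests between genotypes.

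The COS family of membrane proteins encoded near chromosome ends had the highest list median, 0.30 (percentile 99.1), with 5 of 7 measured members higher, none lower and 2 within counting error. COS1 stood at 1.08 (0.68 to 1.499) and COS8 at 0.63, while COS4 was at 0.17 and COS9 at −0.02 (0.14 by the mean). Their median level was 0.57 in WT and 0.84 in the table labelled nhp6ab, although COS1, COS4 and COS8 rested on 1 nucleosome each and family members share sequence. The random lists were not matched on distance to chromosome ends, near which ratios were mostly above 0. The percentile therefore cannot separate the COS family from its position. Purine and pyrimidine synthesis genes followed with 0.12 (percentile 99.6), with 13 of 19 higher and 3 lower. IMD2 at 1.53 and URA3 at 0.99 were highest, and ADE2 at −2.07 and ADE3 at −0.22 lowest. The ADE2 ratio rested on 2 adjacent WT nucleosomes with 14328 and 4069 counts, and without them and their counterparts it was −0.25 by the mean. Genes of the Sir proteins and histone deacetylases had a median of 0.11 (percentile 97.8), with 9 of 13 higher and 2 lower. HST3 at 0.22 and HST1 at 0.15, both homologues of SIR2, were highest. RIF2 (chromosome XII) at −0.29 and SIR4 at −0.15 were lowest, but stood at 0.52 and 0.10 by the mean per nucleosome. By that mean the list lay at percentile 96.98, inside the central range.

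Among the lists on the low side, snoRNA and snRNA genes had a median of −0.34 (percentile 1.08), with 14 of 19 lower and 2 higher. SNR3 was at −0.90 (−1.04 to −0.77) and SNR17A, a U3 snoRNA gene, at −0.71 (−0.12 by the mean), while SNR4 at 0.65 (0.07 by the mean) and SNR7-L at 0.23 were highest. By the mean the list median was −0.17 at percentile 7.19. Proteasome genes had a median of −0.13 (percentile 1.42), with 19 of 32 lower and 4 higher. RPN12 at −0.42 and PRE5 at −0.34 were lowest, and RPT5 at 0.18 and RPT2 at 0.16 highest. None of these genes lie on chromosome XII, and without that chromosome in the comparison the percentile was 2.88, inside the central range. For FACT and nucleosome remodelling genes, −0.09 (percentile 0.41) came from 13 of 22 lower and 5 higher members. POB3, a FACT subunit, was at −0.49 (−0.17 by the mean) and HIR1 at −0.37 (0.08 by the mean, with 19 nucleosomes in WT and 14 in the other table), with HIR2 at 0.27 and MSI1 at 0.16 highest. By the mean this list's median was 0.02 at percentile 10.4, within a random range of 0.0016 to 0.11. It thus stayed on the low side by that measure, but inside the central range.

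Histone genes had lower relative counts per listed nucleosome in the table labelled nhp6ab. Their median level was 0.99 times the table's median in WT and 0.69 in the table labelled nhp6ab, and 7 of 11 were lower and 1 higher by summed counts. The list median was −0.23 by the sum, inside the central range at percentile 9.54, as it was over open reading frames only (percentile 11.63). By the mean per nucleosome, chosen for lists after seeing the data, it was −0.57, below all 10000 random lists. HTA1 (YDR225W, chromosome IV, 915530 to 915928), a histone H2A gene, had the lowest ratio at −1.07 (−1.18 to −0.96), with 2346 and 855 counts over 4 nucleosomes in each table. HHF1 (YBR009C, chromosome II, 255373 to 255684), a histone H4 gene, followed at −0.83 (−0.98 to −0.69) over 3 nucleosomes in each. The linker histone gene HHO1 was highest at 0.18, or −0.04 by the mean, followed by the H2A.Z gene HTZ1 at −0.05. Core histone genes lie in divergent pairs with a shared promoter, so members of a pair share part of their windows, which the random lists do not allow for.

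Genes for the H4K16 acetylation machinery had a median of −0.11 (percentile 6.78), with 7 of 13 lower and 3 higher. EPL1, a subunit of the NuA4 acetyltransferase, stood at −0.60 and SAS2, the catalytic subunit of the SAS acetyltransferase, at −0.56, the latter being 0.25 by the mean. BDF1 (chromosome XII) at 0.48 and DOT1 at 0.14 were highest. Ribosomal protein genes had a low level in both tables, 0.67 and 0.62, and a median ratio of −0.09 (percentile 54.7), with 65 of 138 lower and 36 higher. RPS4B at −1.07 and RPS4A at −0.94, a near-identical pair, were lowest, and RPL32 at 0.69 (0.28 by the mean) came next to RPP0 at the top. Over open reading frames alone, the ribosomal protein median was 0.12, above all 10000 random lists, so that the direction depended on the upstream window. Ribosome biogenesis genes had a median of −0.09 (percentile 5.43), with 22 of 38 lower and 10 higher, SSF1 at 0.79 (0.20 by the mean) and DRS1 (chromosome XII) at 0.35 being highest and CIC1 at −0.49 and UTP10 at −0.43 lowest. Each chromosome's centring on its own median moved this list to percentile 0.38.

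Heat shock and chaperone genes had a median of 0.04 (percentile 92.35), with 11 of 24 higher and 5 lower. HSP104 at 0.56 and HSP60 at 0.39, both on chromosome XII, were highest, and CUR1 at −0.61 (−0.13 by the mean) and SSB1 at −0.57 lowest. By the mean per nucleosome this list lay at percentile 99.69 with a median of 0.13. Genes induced by environmental stress had a median of −0.04 (percentile 29.16), with 7 of 24 higher and 11 lower. UBI4 at 0.83 and GSY2 at 0.48, again on chromosome XII, were highest, and DDR2 at −0.77 and HOR7 at −0.62 lowest, or −0.19 and −0.21 by the mean. In glycolysis the median was 0.03 (percentile 85.9) with 7 of 21 higher and 7 lower, from GPM1, phosphoglycerate mutase, at 0.76 and PDC5 (chromosome XII) at 0.59 to ADH1, alcohol dehydrogenase, at −0.48 (−0.06 by the mean) and GLK1 at −0.24. Hexose transporter genes had a median of −0.02 (percentile 55.3), with 4 of 16 higher and 7 lower. HXT3 (YDR345C, chromosome IV, 1162957 to 1164660), a glucose transporter, was far below the rest by the sum at −2.13 (−2.29 to −1.97), with 2059 counts over 12 nucleosomes in WT and 360 over 5 in the table labelled nhp6ab. By the mean it was −0.87, close to HXT7, which was at −0.78 by sum and mean alike over 1 nucleosome in each table. HXT13 at 0.84 and HXT12 at 0.80 were highest, or 0.10 and 0.21 by the mean.

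Cell wall genes had a median of −0.01 (percentile 64.03), with 7 of 26 higher and 11 lower. CCW12 (YLR110C, chromosome XII, 369697 to 370098), an abundant cell wall mannoprotein gene, was at −2.13 (−2.32 to −1.94) over 5 nucleosomes in each table, with its level at 0.71 in WT and 0.15 in the table labelled nhp6ab, against the shift of its chromosome. CRH1 was at −0.50, and EXG1 (chromosome XII) at 0.76 and UTR2 at 0.57 were highest. The PAU list had a median of −0.01 (percentile 75.95), with 6 of 17 higher and 6 lower, PAU24 at 1.502 and PAU17 (chromosome XII) at 1.07 against PAU20 at −1.23 and TIR3 at −0.38. Though written as a subtelomeric family, the list also holds genes farther in, with PAU17 94933 bp and TIR3 104820 bp from a chromosome end. By the mean PAU17, with 4 and 6 nucleosomes, was at 0.48 and PAU20, with 2 and 1, at −0.23. The flocculin list, which includes FLO8, not itself a flocculin gene and annotated as a pseudogene, lay near 0 (−0.00, percentile 48.1). Of its members 1 of 5 was higher and 1 lower, with FLO11 at 0.08, FLO8 at 0.02, FLO9 at −0.02 and FLO10 at −0.09. By the mean FLO8 was at −0.06 and FLO10 at 0.06. In oxidative phosphorylation the median was −0.02 (percentile 73.9) with 12 of 35 higher and 13 lower. QCR10 at 1.08 had 2 nucleosomes listed in WT and 5 in the table labelled nhp6ab, and by the mean it was −0.24. COX12 (chromosome XII) was at 0.79 (0.38 by the mean), ATP3 at −0.64 (−0.15 by the mean) and CYT1 at −0.40 (0.12 by the mean). Amino acid biosynthesis genes had a median of 0.01 (percentile 74.3), with 18 of 49 higher and 16 lower. Below HIS3 came ASN1 at 0.51, and GCN4, the activator of amino acid synthesis genes, at −0.94 and SER3 at −0.20 were lowest. Ergosterol synthesis genes stood at 0.06 (percentile 93.65), with 9 of 22 higher and 4 lower, ERG3 at 0.57 and HMG2 at 0.41, both on chromosome XII, being highest and ERG9 at −0.33 and ERG11 at −0.24 lowest. By the mean ERG9 and ERG11 were at 0.08 and 0.10, percentiles 65.5 and 70.9 of measured genes.

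In the remaining lists the medians lay inside the central range of the random lists. Mating pheromone genes had a median of −0.02 (percentile 47.2), with 5 of 18 higher and 6 lower, SST2 (chromosome XII) at 0.52 and FAR1 at 0.33 against MFA2 at −0.75 and FUS3 at −0.23. MFA2 had 2 nucleosomes listed in WT and 1 in the table labelled nhp6ab, and was at 0.25 by the mean. Galactose genes had −0.02 (percentile 35.8), with 2 of 7 higher and 2 lower, GAL2 (chromosome XII) at 0.53 and GAL80 at 0.06 against GAL10 at −0.16 and GAL3 at −0.14. Phosphate genes had −0.09 (percentile 8.49), with 4 of 12 higher and 8 lower, PHO89 at 0.19 (−0.01 by the mean) and SPL2 at 0.15 against PHO4 at −0.44 and PHM6 at −0.32. Iron and copper genes had 0.02 (percentile 69.2), with 8 of 20 higher and 6 lower, HMX1 at 0.52 and TIS11 at 0.51, both on chromosome XII, against CTR1 at −0.60 (−0.14 by the mean) and FTR1 at −0.28. DNA replication and repair genes had 0.01 (percentile 54.9), with 12 of 29 higher and 9 lower, MCM5 at 0.48 and CDC45 at 0.33, also on chromosome XII, against CDC6 at −0.30 and RNR2 at −0.23 (0.06 by the mean). Cell cycle genes had 0.01 (percentile 66.9), with 9 of 23 higher and 11 lower, CTS1 (chromosome XII) at 0.58 against CLN2 at −0.28 and CLB2 at −0.27 (0.47 by the mean). Meiosis and sporulation genes had −0.10 (percentile 5.97), with 6 of 22 higher and 13 lower, but 0.10 by the mean at percentile 97.99. IME1, the inducer of meiosis, was highest there at 0.41, followed by RED1 (chromosome XII) at 0.27, and SMK1 at −0.58 and ZIP1 at −0.45 were lowest. The upstream window of SMK1 reaches into NHP6A. It holds the midpoints of 2 WT nucleosomes that overlap NHP6A, with 592 and 693 counts. The nhp6ab nucleosome over NHP6A, at 665690 to 665848 with 260 counts, has its midpoint just outside the window. The SMK1 value thus partly reflects the NHP6A locus and the edge of the window. The RNA polymerase III genes other than tRNA genes had 0.05 (percentile 78.8), with 1 of 4 higher and 1 lower, SNR52 at 0.56, SNR6 (chromosome XII) at 0.17 (1.17 by the mean), RPR1 at −0.07 and SCR1 at −0.34. The sum and the mean per nucleosome gave list medians of opposite sign for 7 of the 28 lists, to which the genome-wide shift of the mean above 0 contributes. Scaling to the median gene turned the medians of the mating pheromone, galactose, hexose transporter, PAU, flocculin, oxidative phosphorylation and cell wall lists above 0, each by less than 0.02. This scaling moves every gene by 0.02 alike and left the percentiles of these lists unchanged, so the turns say nothing about the lists.

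**Figure D4:**
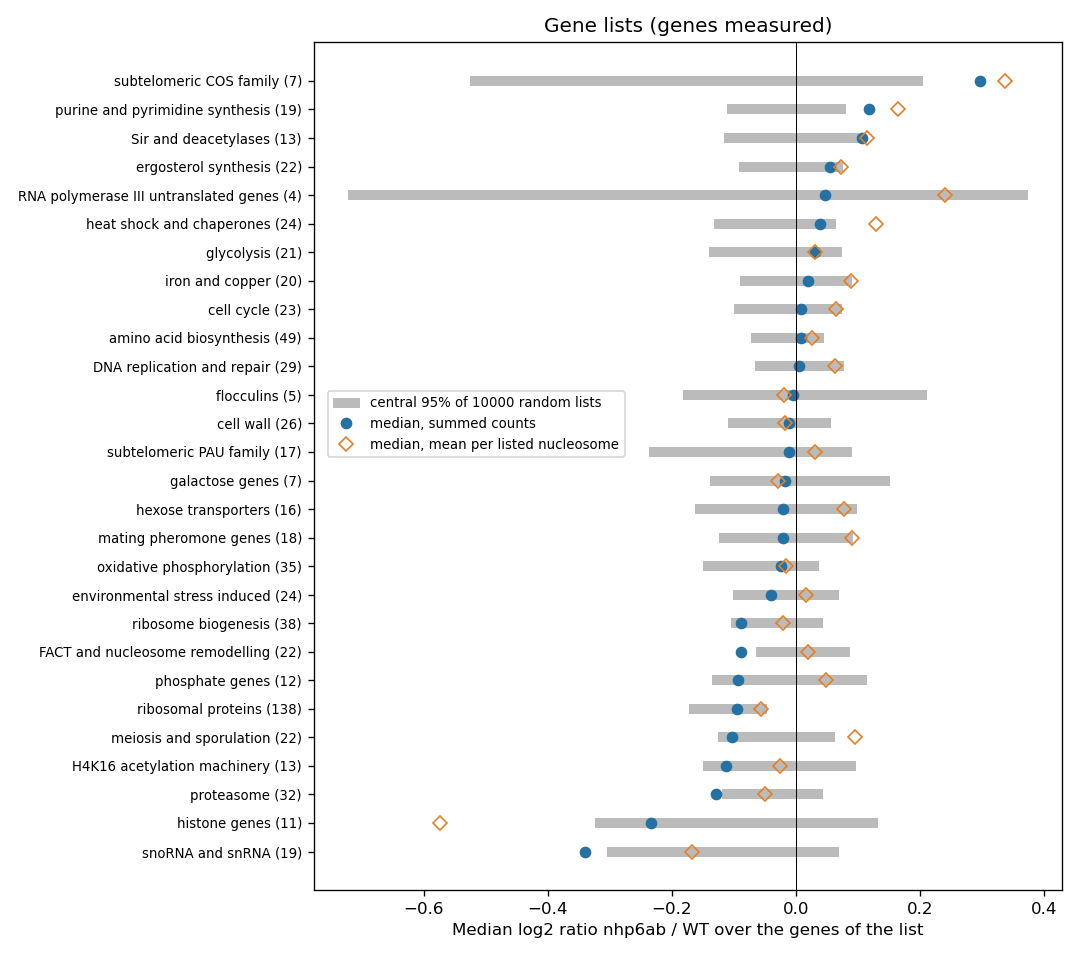
Median log2 ratio of nhp6ab to WT over the measured genes of each list (number in brackets), for summed counts (blue circles) and for the mean per listed nucleosome (orange diamonds), with grey bars for the central 95% of 10000 random lists by summed counts. The COS family at 0.30 lies to the right of its bar and the snoRNA and snRNA list at −0.34 to the left, and the histone list moves from −0.23 to −0.57 between the measures.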

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

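Leaving out chromosome XII, centring each chromosome, and the mean count per listed nucleosome for lists and regions were chosen after seeing the data. No paired analysis was possible because each genotype has a single column of counts for both replicates. For the same reason the replicate block, the second count model and the leaving out of single replicates were not run, and centromeres and LTR and Ty elements were not run for want of coordinates. Depth limits little here beyond short windows, since a typical gene held 4113.5 and 3083.5 counts, whereas the unknown spread between replicates limits every ratio. Of 105 comparisons of a main value with an alternative, 48 kept direction and size, 52 moved and 5 reversed. Of 782 for single genes and lists, the numbers were 487, 288 and 7, with reversals counted only where the main value was called. The sign changed in 86 of the 782, of which 79 had no called main value: 52 of 615 for genes and 34 of 167 for lists changed sign. Scaling to the median gene moved all log2 ratios by 0.02. The mean per nucleosome and paired nucleosomes shift the genome as a whole too, to 0.068 and 0.056 beyond 30 kb from chromosome ends. Some changes of sign in these settings therefore reflect the shared shift. In what follows the cause was not tested unless the setting itself gives it.

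The 20 genes at least 2 times higher became 32 over open reading frames only (5 genes shared), 114 over 500 bp upstream only (6 shared), 13 at a minimum of 500 counts (all among the 20) and 134 at a threshold of 0.58. The 66 lower genes became 69 over open reading frames only (26 shared), 441 over upstream sequence only (31 shared), 39 by the mean per nucleosome (31 shared) and 220 at 0.58. The 164 higher nucleosome pairs became 100 within 25 bp, 2391 at 0.58, 66 without chromosome XII and 61 with each chromosome centred, and the 388 lower pairs became 1519 at 0.58. The minimum count, the threshold, the narrower pairing and the removal of chromosome XII give these changes by construction. For the windows, the mean and the centring the cause was not tested.

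Near chromosome ends, paired nucleosomes gave 0.31 within 5 kb, 0.17 from 5 to 10 kb, 0.099 from 10 to 20 kb and 0.097 from 20 to 30 kb, and reversed the ratio beyond 30 kb to 0.056. The mean per nucleosome gave 0.15, 0.15, 0.11 and 0.11 in the same classes and 0.068 beyond 30 kb, where 57492 of the 60557 WT nucleosomes lie. Median scaling gave 0.15 from 5 to 10 kb, 0.062, 0.049 and, reversed, 0.021 beyond 30 kb. Medians over ends were 0.19 from 5 to 10 kb, 0.0035 from 20 to 30 kb and −0.038 beyond 30 kb. Without chromosome XII the ratio was 0.018 from 10 to 20 kb, reversed to −0.0027 from 20 to 30 kb, and −0.043 beyond. The ratios within 20 kb of ends stayed above 0 in each of these settings, and those farther in changed sign in at least 1. By the mean and for paired nucleosomes, the values to compare with are 0.068 and 0.056 beyond 30 kb. Against these, 10 to 20 kb (0.11 and 0.099) and 20 to 30 kb (0.11 and 0.097) were only slightly higher. The sign beyond 30 kb is set by the scaling and tests nothing, since most listed nucleosomes lie there.

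Upstream of open reading frames the ratio was −0.20 with median scaling, −0.20 over long open reading frames, −0.058 by the mean and −0.25 without chromosome XII. In the same order it was 0.063, 0.057, 0.053 and 5.1e-05 in the first 500 bp, 0.085, 0.084, 0.11 and 0.018 from there to 1000 bp, and 0.033, 0.0070, 0.096 and, reversed, −0.031 beyond 1000 bp. The window around HML was at −1.42 for paired nucleosomes and −1.44 by the mean. Around tRNA genes the ratio was −0.11 with median scaling, −0.065 for paired nucleosomes, −0.072 by the mean and −0.16 without chromosome XII. NHP6A was at −0.80 over the open reading frame and NHP6B at −0.43 by the mean.

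Over gene bodies only, 5 tRNA genes among the 12 highest reversed: YNCP0007C to −0.19, YNCM0035C to −0.32, YNCK0016W to −0.40, YNCB0002W to −0.57 and YNCK0021W to −0.27. By the mean, QCR10 reversed to −0.24. The FACT and nucleosome remodelling list changed sign to 0.020 but stayed on the low side of its random lists, at percentile 10.4. Of the 66 lower genes, 5 turned positive by the mean: HOP2 (0.14), CSN9 (0.31), YNL146C-A (0.38), the tRNA gene YNCB0012W (0.47) and HSH49 (0.22). The lists for environmental stress, phosphate, mating pheromone, hexose transporters, PAU genes and meiosis and sporulation, which were not called, also turned positive by the mean (0.016 to 0.095). Random lists move up by this measure too, and the percentiles of these lists ran from 25.9 (environmental stress) to 97.99 (meiosis and sporulation). Over open reading frames 5 lists lay above the central 95% of random lists instead of 3. The COS and the purine and pyrimidine lists lay above it in all 6 alternative settings. No setting matched the random lists on distance to chromosome ends, so none separates the COS family from its position near ends. The proteasome list lay inside it over open reading frames (percentile 9.87), with centring (3.84) and without chromosome XII (2.88).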

Other observations

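The tests of chromosome XII and HIS3 and URA3 that rest on listed intervals, on bins and on input, the test of repeated sequences on chromosome III, and the ADE2 value were chosen after the results were seen, while the tests of class ranges and marker flanks were laid down before.

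FAS1, a fatty acid synthase gene on chromosome XI (100671 to 106826), was chosen after its values were seen because 2 of its nucleosomes were among the 10 highest pairs. Its log2 ratio was 0.56 (0.52 to 0.60) over 44 and 43 nucleosomes, and its level was 0.54 times the table's median in WT and 0.78 in the table labelled nhp6ab. The neighbours of HIS3, also chosen after their values were seen, were MRM1 at 0.48 and DED1 at 0.57, over windows beside HIS3 that may share its nucleosomes. Of other genes used as markers in laboratory strains, LEU2 was at −0.19 over its open reading frame, TRP1 at −0.42, LYS2 at 0.11, MET17 (chromosome XII) at 0.20 and CAN1 at 0.16, against 1.57 for HIS3 and 1.04 for URA3. By the mean LEU2 was at 0.01, TRP1 at −0.42, LYS2 at 0.11, MET17 at 0.37 and CAN1 at 0.02, against 1.16 for HIS3 and 0.78 for URA3. By the mean count per nucleosome HIS3 lay at percentile 99.9 and URA3 at 99.8 of all genes, and TRP1 at 3.56. The histone H3 genes HHT1 and HHT2, with −0.25 and −0.23 by the sum, had −0.57 and −0.82 by the mean, with 5 and 6 nucleosomes listed against 4 in WT. TEF1, the partner of TEF2, had 0.66 by the sum and −0.93 by the mean.

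In ADE2 on chromosome XV, the WT nucleosomes at 565341 to 565501 and 565205 to 565325 held 14328 and 4069 counts, 32.4 and 9.21 times the table's median, against 315 and 309 in their nhp6ab counterparts. Without them and the 4 nhp6ab nucleosomes that overlap them, the log2 ratio of means was −0.25.

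Chromosome XII was higher in the table labelled nhp6ab by a median log2 shift of 0.42 against the other chromosomes over 4449 matched nucleosomes, or 1.34-fold. More listed nucleosomes would need a larger share of intervals there, but the log2 ratio of shares was −0.017, and a few heavily counted intervals or the rDNA are excluded by bins, since 100% of the 42 bins lay above the 95th percentile of the others. Extra copies of the chromosome in part of the nhp6ab cells predict a shift of 1 size in every class of nucleosome, and over 10 classes of position and WT level the shifts ran from 0.35 to 0.44, a range of 0.092. A candidate explanation is therefore a gain of chromosome XII in part of the culture or in 1 replicate. More H4K16 acetylation along the whole chromosome cannot be told apart from it by the shift of 0.42 alone, because no input reads were used here.

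The left arm of chromosome III from 15 to 85 kb was high in both tables, at 2.06 times the level of other chromosomes in WT and 2.10 in the table labelled nhp6ab, against 1.03 beyond 100 kb in both. A candidate explanation is an extra copy of this segment in cells of both genotypes, for which the levels of all position classes should be alike, and in WT they ranged over 0.81 in log2. That range rested on a class of 14 nucleosomes at 0.27, with the other 4 classes between 0.99 and 1.08, and its bootstrap interval of 0.35 to 1.58 spans the limit of 0.5, so an extra copy stays open. Reads of repeated sequences placed here would fall on part of the intervals, and 78.9% of the intervals exceeded 1.5 times the table's median, which lies between the limits set for and against. No biological explanation was tested, since both genotypes share the pattern.

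HIS3 and URA3 had log2 ratios of 1.57 and 1.04 over their open reading frames. The values of the neighbours MRM1 (0.48) and DED1 (0.57) include upstream sequence beside HIS3 and cannot be read as separate rises. From 1 to 3 kb out, the left flank of HIS3 was at 0.05 and the right flank at 0.35. A larger number of listed nucleosomes is excluded as the whole cause, because the lower of the HIS3 and URA3 ratios of mean count per nucleosome was 0.78. Marker genes inserted elsewhere in the nhp6ab genome predict raised genes within flat flanks, and the highest of the 4 flanks from 1 to 3 kb was 0.35, below the limit of 0.58, so insertion of both markers is a candidate explanation. NHP6A and NHP6B kept 57.4% and 83.6% of expectation, and where such markers would lie was not tested. Higher acetylation at these genes in the nhp6ab cells was not tested and stays open without input reads.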
